A study of Mus musculus with 6 samples.

How the data were processed

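Per the labels' protocols, pan-B cells were isolated from spleens with a magnetic kit on day 8 after the injection, and libraries were made from 1 µg of total RNA with a TruSeq RNA kit, which does not mark the strand. Reads of overlapping or antisense genes therefore cannot be told apart. The submitters' processing notes name CASAVA 1.8.2, STAR and DESeq2 without a role, and the build mm9. The counting tool, the annotation release and any filter are not given in the sources used here. The gene coordinates in the deposited files are those of GRCm38 and not mm9: of 35275 listed genes, 34490 have an identifier in the GENCODE annotation of GRCm38 and 24932 of these have exactly its start and end. Coordinates are printed as the files give them.

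The authors deposited FPKM values per gene and library, in a table with gene names and in one without, which are equal in every cell, and also a table of FPKM means with the columns MUT and WT. The gene lengths used for FPKM are a deposited column too. FPKM times gene length summed to the same total in every library, and division by the smallest step gave whole reads for 100% of the values (tolerance 0.01 reads). The recovered totals were 25531391, 24320080 and 27589963 reads for the libraries labelled WT replicates 1, 2 and 3, and 27174790, 24835367 and 27866611 reads for CD40LΔ5 replicates 1, 2 and 3. 1 read equals 0.0359 to 0.0411 FPKM for a gene of 1 kb, which limits what can be said of genes near that level. Each column of the table of means was matched to the 3 libraries whose mean it equals, to within 3.33e-08 FPKM. No other set of 3 libraries was assumed for it.

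Groups were taken from the sample labels, 3 libraries each, without covariates. The test was limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a trend) on log2(FPKM + 1), two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Genes with a mean of at least 1 FPKM over the 6 libraries entered, which left 11252. Log2 differences are on the log2(FPKM + 1) scale, which understates the change of low genes. Cd40lg lay under that level and was compared by an exact two-sided permutation test of mean FPKM, which cannot give a p under 0.1 with 3 against 3. A count model on the recovered reads, foreseen before the values were examined, was not run, since the deposited unit is FPKM. limma voom on these reads was run in its place.

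Before the data were examined, 32 gene lists with 578 entries were fixed, of which 574 were found. Many symbols stand in more than 1 list, such as 16 of the 28 CD40 and NF-kB targets, 9 of the 14 light zone genes and 4 of the 20 germinal centre genes, so lists are not independent. Lists with at least 3 tested genes were compared by camera with a preset correlation of 0.01, leaving out the sex-linked list, and adjusted over the 30 lists tested. camera with an estimated correlation and fry were alternatives.

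The rule for named genes was fixed then too. It takes Cd40lg, and among called genes with groups that do not overlap the 12 largest changes in each direction, without immunoglobulin variable segments and predicted genes. With fewer than 5 called genes in a direction it takes the 10 smallest unadjusted p in that direction, with values and no call. It also takes up to 4 members of each list by smallest p, and up to 3 of the most abundant members of the lists of other cell types and of the sex-linked list. Genes outside the rule are marked in the text.

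The comparison by the sets of the table of means, and all of its alternatives, were added after seeing the data, as were voom, values corrected for gene length (loess with a span of 0.3 on log length, per library), and a comparison of the 4 libraries WT replicates 1 and 2 and CD40LΔ5 replicates 1 and 3. The labels and the table split these 4 the same way but under opposite names. Settings fixed before the data were examined were other pseudocounts, filters, scalings and variance settings, a replicate block, a version without immunoglobulin and histone genes, and leaving out each library.

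The procedure was tested on simulated data, with 50 genes changed at each fold size among 11252. The changed genes were drawn only from those with a mean log2(FPKM + 1) above 2, so the shares recovered do not cover lower genes. With the label groups, 46% of genes changed 1.5-fold, 76% at 2-fold, 92% at 4-fold and 96% at 8-fold were recovered, with 12 false calls. With the table sets the shares were 50%, 90%, 92% and 98%, with 12 false calls. The genes of all fold sizes were changed in the same simulated data. The adjustment is stricter where few genes change, so the shares overstate what would be recovered then. The noise of each simulated gene had the spread of the real gene within groups but was drawn independently of other genes, so shifts shared by many genes of a library were not part of this test.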

Results

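The data are gene expression values, in FPKM, of B cells from the spleens of wild-type (WT) mice and of mice that carry an altered CD40 ligand, CD40LΔ5. Per the labels, the mice were 6 to 8 weeks old and of the strain C57BL/6. They received sheep red blood cells (SRBC), a T cell-dependent antigen that drives germinal centre responses in the spleen, and were sampled on day 8. There were 3 libraries per group. The labels do not say whether each library came from its own animal. The p-values of single genes therefore measure the spread between these 6 libraries. Those of camera at the preset correlation also treat the genes of a list as nearly independent. Reads on genes lay between 24320080 and 27866611 per library. The comparison asks how the B cell transcriptome differs between the 2 genotypes during the response.

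The placement of the libraries in groups was not the same in every deposited source, and this bears on all directions given here. The authors' deposited table of group means holds a MUT and a WT column. Its MUT column was the mean of the libraries labelled WT replicate 1, WT replicate 2 and CD40LΔ5 replicate 2, to within 3.33e-08 FPKM at every gene. Its WT column was the mean of the libraries labelled WT replicate 3, CD40LΔ5 replicate 1 and CD40LΔ5 replicate 3. The labels and the table thus placed 2 of the 6 libraries alike, namely WT replicate 3 and CD40LΔ5 replicate 2. The deposited values per library also list the libraries averaged as MUT first and those averaged as WT after them. The labels are used below for the main comparison. The sets of the table follow as a second comparison, added after the data were examined, and a library name is always the name that its label gives.

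Cd40lg encodes CD40 ligand, the T cell surface protein that engages CD40 on B cells (ENSMUSG00000031132, chromosome X, 57212143 to 57224042, plus strand). It lay near the detection limit in these B cell libraries, at 0.53, 0.43 and 0.20 FPKM in WT replicates 1, 2 and 3 and at 0.12, 0.48 and 0.14 FPKM in CD40LΔ5 replicates 1, 2 and 3. These values rest on 4 to 17 reads per library. By the labels the means were 0.388 ± 0.168 FPKM for WT and 0.248 ± 0.204 FPKM for CD40LΔ5 (SD, n = 3; exact two-sided permutation p = 0.3). By the table the libraries averaged as MUT held 0.481 ± 0.0526 FPKM and those averaged as WT 0.155 ± 0.0437 FPKM (SD, n = 3; exact p = 0.1, the smallest that 3 against 3 can give). The direction of the difference therefore turned with the grouping, and every direction below is that of libraries labelled or averaged in a given way. Other T cell genes turned in the same way: 14 of 16 tested were lower by the labels and 14 of 16 higher by the table. The Cd40lg values thus cannot be told apart from a difference in T cell content between the libraries. A change within the coding sequence that leaves the transcript in place would not show in a value per gene.

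Between the libraries labelled CD40LΔ5 and WT, the genes of smallest p ranged from low to high expression, and none passed the test. Ccdc74a, which had the smallest p on the higher side, measured 1.82 ± 0.312 FPKM in the libraries labelled CD40LΔ5 and 0.785 ± 0.131 FPKM in those labelled WT (SD, n = 3). Cxcr4, the chemokine receptor that holds B cells in the dark zone of the germinal centre, measured 141 ± 19.3 FPKM in the libraries labelled CD40LΔ5 and 102 ± 10.1 FPKM in those labelled WT (SD, n = 3; log2 difference 0.46 ± 0.13 SE). Ddit4, a stress-responsive inhibitor of mTORC1, measured 69.3 ± 10.1 against 51.3 ± 2.06 FPKM. Among genes with lower values, Gadd45g measured 20.6 ± 1.32 against 28.1 ± 5.16 FPKM, Id2, an inhibitor of E-protein transcription factors, 8.11 ± 0.684 against 10.4 ± 1.16 FPKM, and Thyn1 0.817 ± 0.206 against 1.74 ± 0.246 FPKM. The rule for named genes also takes Ccdc74a, Hivep3, Fryl, Zzef1, Akap9, Trrap, Slc25a18 and Lrrc63 on the higher side, with log2 differences of 0.28 (Zzef1) to 0.66 (Ccdc74a). On the lower side it takes, among others, Nthl1, Tmem238, Rps4l, Hist1h2bg, Uck2 and Hist1h2bl, with log2 differences of -0.57 (Hist1h2bg) to -0.27 (Tmem238). The entry named Uck2 is listed with a length of only 93 bases and held 39 to 65 reads per library. With limma on log2(FPKM + 1), 0 of 11252 genes passed an adjusted p of 0.05, and the smallest adjusted p was 0.999993. At an unadjusted p under 0.05 there were 139 genes, 103 with higher and 36 with lower values, where chance alone gives about 563. limma voom on the whole reads recovered from the FPKM values also called 0 genes.

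Erythroid, macrophage and plasma cell genes had lower values in the libraries labelled CD40LΔ5, while 12 of 14 neutrophil genes had higher values without a call (median log2 difference 0.16, camera adjusted p = 0.685). All 17 tested genes of the erythroid list were lower (median log2 difference -0.29), with Slc4a1, the band 3 anion exchanger of red cells, at 2.82 ± 2.85 against 5.35 ± 2.97 FPKM (SD, n = 3). All 16 of the monocyte and macrophage list were lower (median -0.29), among them Hmox1, the haem oxygenase of red pulp macrophages, at 29.9 ± 2.82 against 48.0 ± 33.2 FPKM. In the plasma cell list 23 of 24 genes were lower (median -0.25), such as Prdm1, the regulator of plasma cell differentiation, at 2.02 ± 1.07 against 2.82 ± 0.967 FPKM. Of the oxidative phosphorylation list 21 of 22 were lower (median -0.11), such as Ndufa2 at 117 ± 8.73 against 131 ± 14.3 FPKM. The limma camera test with a preset correlation of 0.01 called 8 of 30 lists, all lower. The adjusted p was 3.3e-05 for erythroid, 9.6e-05 for both monocyte and macrophage and oxidative phosphorylation, and 0.000802 for plasma cell genes. It was 0.00131 for endoplasmic reticulum folding, 0.0417 for MYC targets and for T cell genes, and 0.0427 for glycolysis. No single gene of any list passed, either over all genes or adjusted over the list alone. With an estimated correlation none of the 8 calls held (adjusted p = 0.879), and each of the 8 was lost when some single library was left out. The estimated correlation within these lists was 0.16 (MYC targets) to 0.88 (monocyte and macrophage), against the preset 0.01. The camera adjusted p became 0.408 for erythroid genes without CD40LΔ5 replicate 1 and 0.757 for macrophage genes without WT replicate 1, both with the direction turned. It became 0.353 for oxidative phosphorylation and 0.680 for T cell genes without WT replicate 2, which left 4 lists called, and 0.942 for plasma cell genes (direction turned) and 0.850 for endoplasmic reticulum folding without WT replicate 3. Without CD40LΔ5 replicate 2 it became 0.679 for MYC targets and 0.704 for glycolysis, the latter turned. Removal of the trend with gene length also ended the calls of T cell genes (camera adjusted p = 0.239) and glycolysis (adjusted p = 0.126). Their mean log2 differences hardly changed, from -0.07 to -0.06 for T cell genes and from -0.05 to -0.06 for glycolysis.

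The spread within each label was wide for several genes of the response itself. S1pr2, a receptor that confines germinal centre B cells, stood at 0.835, 15.9 and 19.5 FPKM in WT replicates 1, 2 and 3 and at 21.3, 3.90 and 9.18 FPKM in CD40LΔ5 replicates 1, 2 and 3. Ighg1, the constant region of IgG1, spanned 149 to 26754 FPKM among the libraries labelled WT and 111 to 21225 FPKM among those labelled CD40LΔ5. Igj, the joining chain of secreted antibody, stood at 816, 3627 and 3523 FPKM in the first label and at 1404, 653 and 3495 FPKM in the second. WT replicate 1 and CD40LΔ5 replicate 2 were thus the lowest of their label for all 3 genes. S1pr2 and Igj were chosen after their values were seen. Some other genes of the germinal centre list varied little, such as Lmo2 at 100 to 131 FPKM and Pou2af1 at 223 to 296 FPKM over the 6 libraries. By the labels the germinal centre list had a median log2 difference of 0.06 over 18 genes while the camera direction was lower (adjusted p = 0.718), and the dark zone list -0.00 over 14 genes (adjusted p = 0.718). The cell cycle list had a median of -0.06 over 39 genes (adjusted p = 0.0620).

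**Figure D1:**
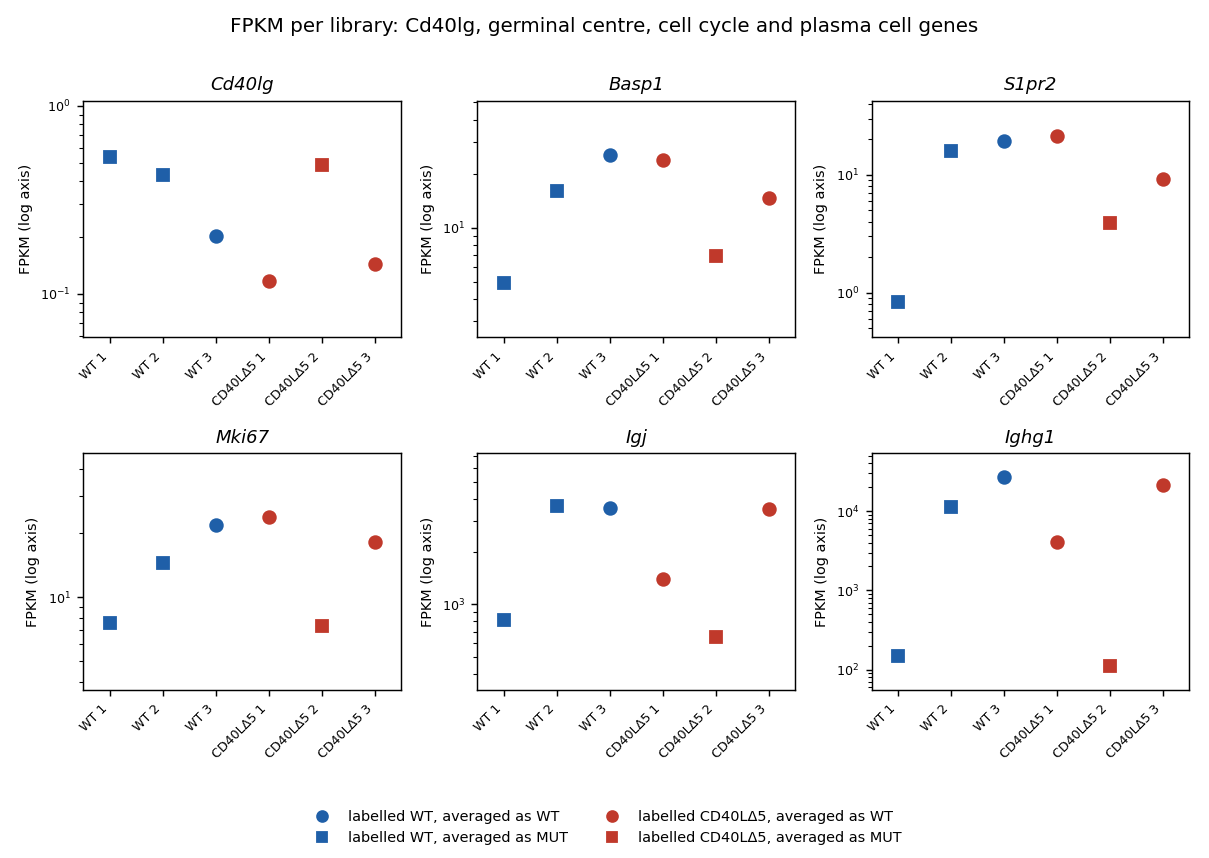
FPKM on a log axis for 6 genes, 1 point per library; colour gives the label (blue WT, red CD40LΔ5) and shape the column of the deposited table of means in which the library was averaged (circle WT, square MUT). S1pr2 runs from 0.835 FPKM in WT replicate 1 to 21.3 FPKM in CD40LΔ5 replicate 1, and both labels hold libraries with low and high Ighg1.

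In the sets of the authors' deposited table, genes of the germinal centre, of proliferation and of antibody secretion had lower means in the libraries averaged as MUT. Mki67, a marker of cycling cells, measured 9.79 ± 4.05 FPKM in these and 21.3 ± 2.80 FPKM in the libraries averaged as WT (SD, n = 3; log2 difference -1.10 ± 0.24 SE). Of the cell cycle list 37 of 39 genes were lower (median -0.50), and 18 were called lower adjusted over the list alone. All 14 dark zone genes were lower (median -0.67, 10 called over the list alone), such as Plk1, the mitotic kinase, at 7.42 ± 3.23 against 14.7 ± 3.21 FPKM. Many of these genes serve in mitosis like Plk1, so this list is close to that of the cell cycle. Of its other members, Cxcr4 and Foxo1 changed little (log2 difference -0.11 and -0.06), while Polh was lower by more (-0.65). Germinal centre genes were lower in 16 of 18 cases (median -0.89, none called over the list alone), with Basp1 at 9.34 ± 5.96 against 21.4 ± 5.83 FPKM and Polh, the polymerase of hypermutation, at 9.29 ± 0.686 against 15.5 ± 3.97 FPKM. In the plasma cell list 23 of 24 were lower (median -0.61), such as Edem1 at 48.4 ± 18.9 against 79.0 ± 16.2 FPKM. All 6 switched constant regions were lower (median -1.53), with Ighg1 at 3797 ± 6351 against 17344 ± 11837 FPKM. Yet WT replicate 2, averaged as MUT, had the highest Ighg2b, Ighg2c and Ighg3 of all libraries (4206, 878 and 1985 FPKM). These genes and Ighg1 were lowest in CD40LΔ5 replicate 2 and next lowest in WT replicate 1. Igha did not follow this, at 733 FPKM in WT replicate 1. Basp1 was also higher in WT replicate 2 (16.1 FPKM) than in CD40LΔ5 replicate 3 (14.7 FPKM), which was averaged as WT. Neutrophil genes were lower in the libraries averaged as MUT too (11 of 14, median -1.33), with Mpo at 1.74 ± 0.703 against 13.5 ± 9.62 FPKM. The high values of Mpo lay in WT replicate 3 and CD40LΔ5 replicate 3. No member of these lists passed over all genes, and with an estimated correlation none of these lists was called (camera adjusted p = 0.611 for neutrophil genes and 0.505 for the others).

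Interferon-response genes and genes of cytotoxic lymphocytes were higher in the libraries averaged as MUT. Of 28 interferon-response genes 27 were higher (median 0.71, 6 called adjusted over the list alone; camera adjusted p = 0.505 with an estimated correlation). Irf7, the transcription factor that amplifies type I interferon, measured 28.1 ± 13.4 against 11.3 ± 0.589 FPKM (SD, n = 3), and Rtp4 14.6 ± 9.18 against 4.49 ± 0.663 FPKM, both with their highest value in CD40LΔ5 replicate 2 (43.6 and 25.2 FPKM). All 10 natural killer cell genes were higher (median 0.57, 7 called over the list alone; adjusted p = 0.505 with an estimated correlation), such as Gzma, a granule protease, at 22.1 ± 0.434 against 8.45 ± 1.79 FPKM and Prf1, perforin, at 4.55 ± 0.279 against 2.80 ± 0.334 FPKM. All 16 monocyte and macrophage genes were higher as well (median 0.57; adjusted p = 0.612 with an estimated correlation), with Cd68 at 13.3 ± 2.46 against 9.39 ± 1.27 FPKM, and so were 14 of 16 T cell genes (median 0.17, 3 called over the list alone; adjusted p = 0.611 with an estimated correlation), with Cd3d at 4.41 ± 0.741 against 2.46 ± 0.0741 FPKM. The marginal zone marker Cd1d1 measured 33.4 ± 1.94 against 19.7 ± 2.49 FPKM, while the marginal zone list as a whole was not called (camera adjusted p = 0.224; 3 genes higher adjusted over the list alone).

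The camera test called 14 of 30 lists in these sets. Lower were cell cycle (adjusted p = 2.7e-21), plasma cell (1.3e-10), dark zone (1.5e-10), endoplasmic reticulum folding (1.2e-09), germinal centre (4.3e-08), neutrophil (0.000143), switched constant region (0.00110) and glycolysis genes (0.00396). Higher were interferon response (1.1e-09), natural killer cell (1.2e-07), monocyte and macrophage (0.000405), T cell (0.0295), erythroid (0.0349) and stroma and endothelium genes (0.0349). With an estimated correlation none of the 14 was called (adjusted p = 0.505 to 0.739), and fry, the rotation test of limma, called none. That correlation ran from -0.03 (stroma and endothelium) to 0.84 (cell cycle, and monocyte and macrophage), against the preset 0.01. Of the 14 calls at the preset correlation, 9 held whichever library was left out, and the others did not. Each of these fits kept WT replicate 1 or CD40LΔ5 replicate 2, the libraries with the lowest Ighg1 and S1pr2. The 9 calls therefore do not show that WT replicate 2 shares the difference. A split of WT replicates 1 and 3 and CD40LΔ5 replicate 2 against the rest, which neither source gives, called 16 lists. The camera adjusted p became 0.0797 for glycolysis without CD40LΔ5 replicate 2, 0.277 for T cell genes without WT replicate 2, 0.0690 for neutrophil genes without CD40LΔ5 replicate 3, 0.786 for erythroid genes without CD40LΔ5 replicate 1 (direction turned) and 0.137 for stroma genes without WT replicate 1.

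**Figure D2:**
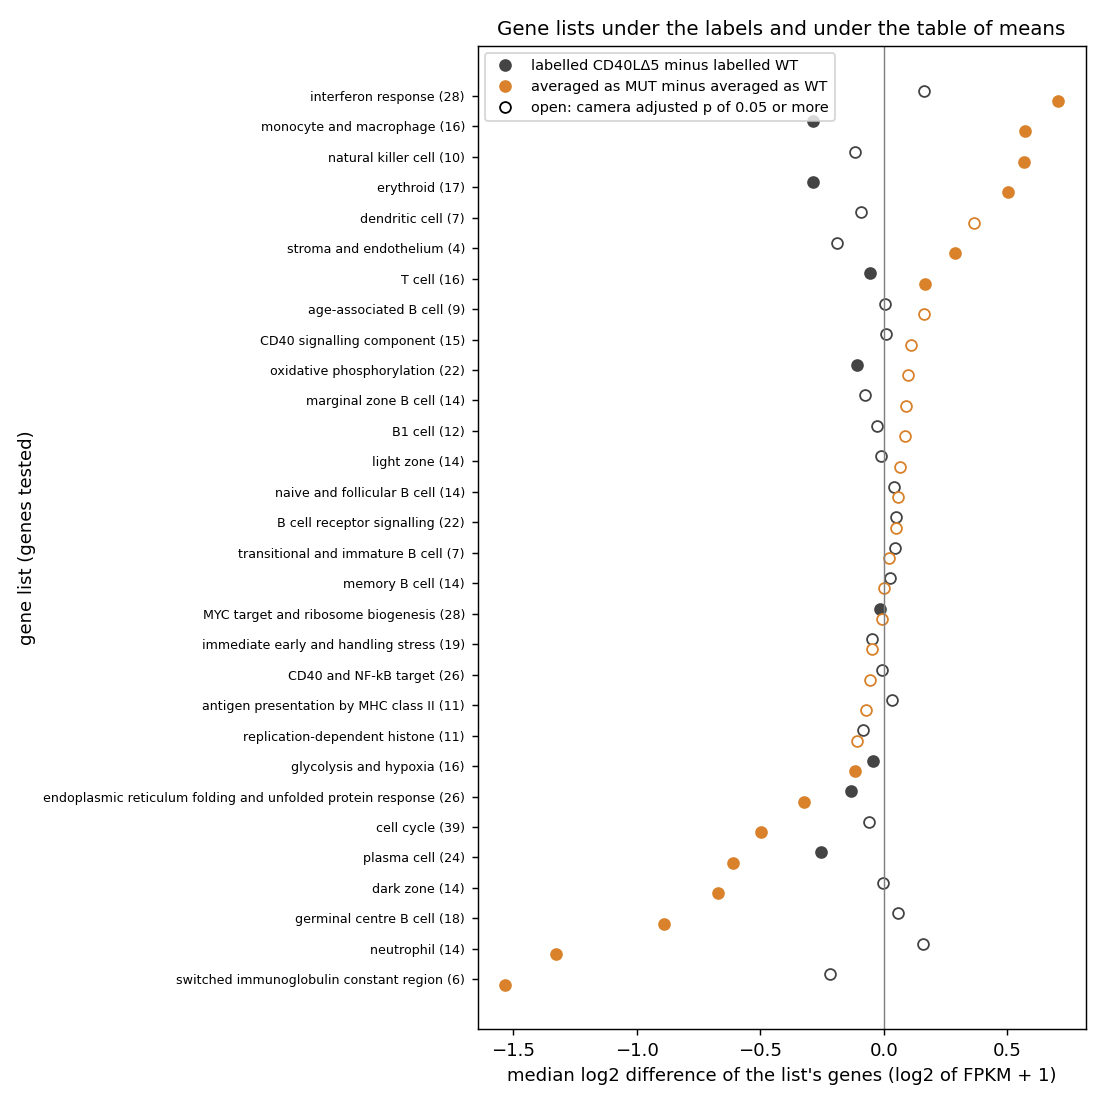
Median log2 difference of each gene list, on the log2(FPKM + 1) scale, with the number of genes tested in parentheses; grey points compare libraries by label (CD40LΔ5 minus WT), orange points by the deposited table (MUT minus WT), and filled points have a camera adjusted p under 0.05. Germinal centre genes lie at 0.06 by the labels and at -0.89 by the table.

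Of the 2 comparisons of all 6 libraries, only that by the table had single genes that passed. Map3k19, a kinase gene (ENSMUSG00000051590, chromosome 1, 127815253 to 127840321, minus strand), stood at 2.01, 2.34 and 2.89 FPKM in the libraries averaged as MUT and at 0.03, 0.04 and 0.06 FPKM in those averaged as WT (log2 difference 1.70 ± 0.15 SE; limma adjusted p = 0.0293). Rgs18, a regulator of G-protein signalling (ENSMUSG00000026357, chromosome 1, 144752683 to 144775435, minus strand), measured 5.06 ± 0.564 against 1.12 ± 0.213 FPKM (SD, n = 3; log2 difference 1.52 ± 0.12 SE; limma adjusted p = 0.0293). The remaining one was Ighd5-3, a diversity segment listed with a length of 10 bases, whose call (limma adjusted p = 0.00304) rests on 2 or 3 reads per library averaged as WT and 0 in those averaged as MUT. As a segment it lies outside the rule for named genes and was named after its values were seen. Of the further genes that the rule names, Hspa1a, an inducible heat shock protein, measured 9.17 ± 3.48 against 1.66 ± 0.0449 FPKM (limma adjusted p = 0.135), Tmem163, near Map3k19 on chromosome 1 (127486546 to 127679548), 23.4 ± 0.636 against 39.5 ± 2.81 FPKM (adjusted p = 0.0677) and Ctse, cathepsin E, 66.8 ± 3.35 against 112 ± 10.8 FPKM (adjusted p = 0.135). At an unadjusted p under 0.05 there were 1463 genes, 1057 higher and 406 lower in the libraries averaged as MUT. The count of 3 ranged from 1 to 16 when 1 library was left out. It was 13 without WT replicate 2, with Ighg3, Eaf2 and Mki67 called lower, 16 without CD40LΔ5 replicate 1, with Mpo, Elane, Prtn3 and Ctsg called lower, and 1 without CD40LΔ5 replicate 2. These further genes were chosen after their values were seen. Map3k19 kept its call in 1 of the 6 fits that left out a library, that without CD40LΔ5 replicate 1, and was under the level for testing without CD40LΔ5 replicate 2. Its limma adjusted p was 0.0692 without WT replicate 1, 0.0575 without WT replicate 2, 0.177 without WT replicate 3 and 0.0837 without CD40LΔ5 replicate 3, while its log2 difference stayed between 1.69 and 1.79. Rgs18 kept its call in 2 of the 6, those without WT replicate 2 and without CD40LΔ5 replicate 1. Its limma adjusted p was 0.127 without WT replicate 1, 0.177 without WT replicate 3, 0.183 without CD40LΔ5 replicate 2 and 0.0521 without CD40LΔ5 replicate 3, while its log2 difference stayed between 1.46 and 1.60.

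Targets of the CD40 pathway went both ways under either grouping, and neither CD40 list was called with all 6 libraries. The list of CD40 and NF-kB targets had a median log2 difference of -0.01 over 26 genes by the labels (camera adjusted p = 0.309) and -0.05 by the table (adjusted p = 0.0953). Ebi3, a cytokine subunit induced by CD40, measured 3.98 ± 0.541 FPKM in libraries labelled CD40LΔ5 and 4.73 ± 0.831 FPKM in those labelled WT, and 4.88 ± 0.677 FPKM in libraries averaged as MUT and 3.83 ± 0.353 FPKM in those averaged as WT (SD, n = 3). Ccl22, a chemokine that B cells make after T cell help, measured 1.48 ± 0.763 against 1.78 ± 0.914 FPKM by the labels and 1.05 ± 0.346 against 2.21 ± 0.595 FPKM by the table. Cd40, the receptor, measured 42.6 ± 6.09 against 43.0 ± 7.61 FPKM by the labels and 48.0 ± 1.85 against 37.5 ± 2.96 FPKM by the table. The components of CD40 signalling had a median of 0.01 by the labels (adjusted p = 0.867) and 0.11 by the table, where 14 of 15 genes were higher (adjusted p = 0.0953). Leaving out 1 library brought calls: the camera adjusted p of the targets was 0.0170 by the labels without CD40LΔ5 replicate 1 and 0.0139 by the table without CD40LΔ5 replicate 3, lower in both. That of the components was 0.0132 without WT replicate 2 and 0.0483 without CD40LΔ5 replicate 1, higher in both, by the table. With all 6 libraries none of these genes passed over all genes or adjusted over the list alone.

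Markers of other cells were present in every library and differed between libraries of one label. Some genes of the neutrophil list stood apart in WT replicate 3 and CD40LΔ5 replicate 3. Mpo, the peroxidase of neutrophil granules, stood at 19.5 and 18.5 FPKM in these and at 0.987 to 2.38 FPKM in the others, and Elane, neutrophil elastase, at 30.4 and 26.8 against 2.10 to 3.53 FPKM. S100a8 reached 99.2 and 199 FPKM there against 14.3 to 30.2 FPKM elsewhere. Retnlg and Mmp9 of the same list were instead highest in WT replicate 1 (36.3 and 1.63 FPKM) and CD40LΔ5 replicate 2 (36.0 and 2.30 FPKM). The macrophage gene C1qa was highest in WT replicate 1, at 48.2 FPKM against 8.96 to 19.1 FPKM in the others. Haemoglobin (Hbb-bs) lay between 153 FPKM in CD40LΔ5 replicate 1 and 563 FPKM in CD40LΔ5 replicate 3. T cell receptor genes were low in all libraries, with Trbc2 at 11.8 to 15.9 FPKM. Immunoglobulin genes took 2.19% to 8.59% of the reads. All 6 libraries held Xist, the transcript of the inactive X chromosome (19.0 to 51.9 FPKM), and the Y-linked Ddx3y and Eif2s3y stood at 0.03 FPKM or less.

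Genes of the major histocompatibility complex (MHC) differed widely between libraries of the same label. H2-Aa, the alpha chain of the class II molecule I-A (chromosome 17, 34282744 to 34287827, minus strand), stood at 2059, 497 and 2958 FPKM in WT replicates 1, 2 and 3 and at 3072, 1982 and 1773 FPKM in CD40LΔ5 replicates 1, 2 and 3. H2-Ab1, its beta chain, stood at 2146, 950 and 3106 FPKM and at 3170, 2025 and 2093 FPKM. The class I gene H2-K1 (chromosome 17, 33996017 to 34000333, minus strand), stood at 727, 66.0 and 1122 FPKM and at 1084, 738 and 557 FPKM. H2-Eb1, the next class II gene on that chromosome (34305877 to 34316199), stayed between 2576 and 3009 FPKM, and Cd74, the invariant chain, between 8070 and 9546 FPKM. H2-K1, H2-T23, H2-Eb1 and Cd74 were chosen after their values were seen. The list of antigen presentation by MHC class II was called neither by the labels (median log2 difference 0.04 over 11 genes, camera adjusted p = 0.572) nor by the table (median -0.07, adjusted p = 0.0538).

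**Figure D3:**
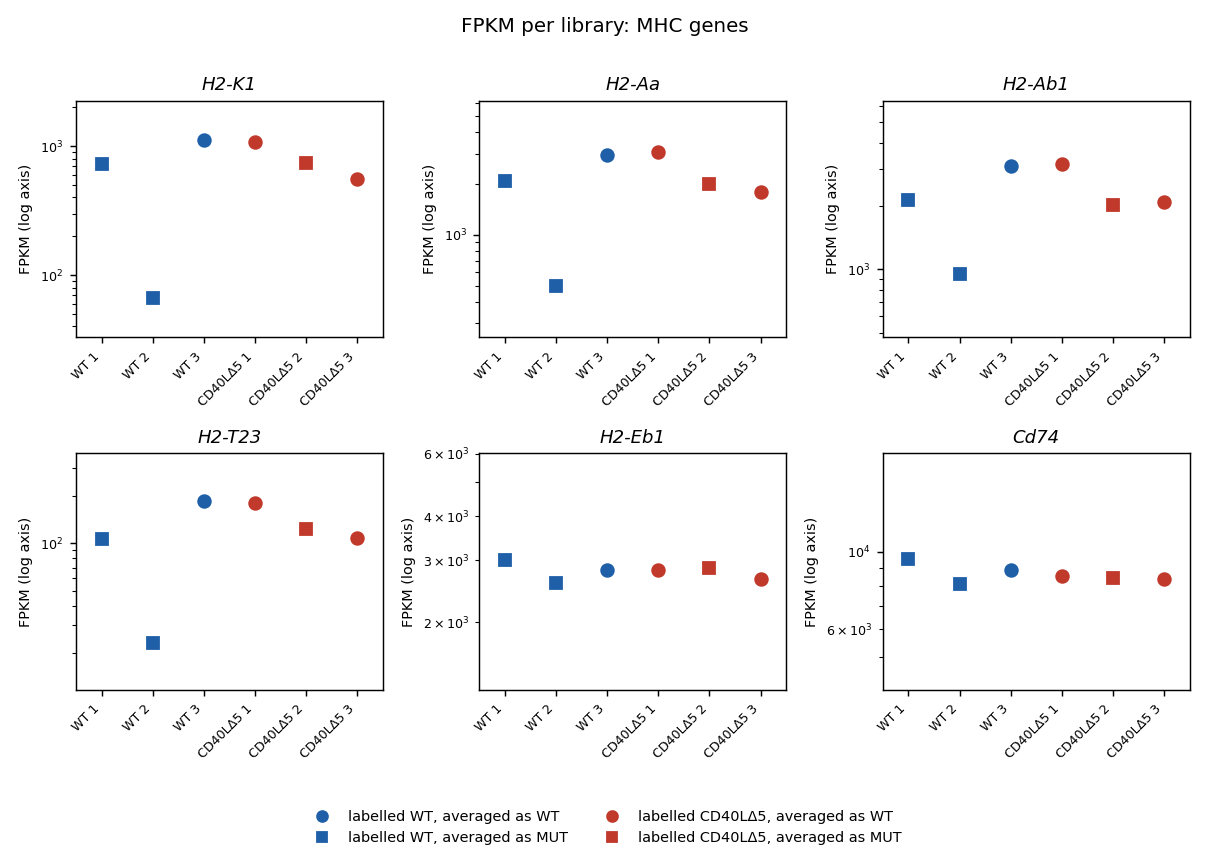
FPKM on a log axis for 6 MHC genes, 1 point per library, with colours for the label and shapes for the column of the deposited table as in the plot of response genes. H2-K1, H2-Aa, H2-Ab1 and H2-T23 were lowest in WT replicate 2 (66.0, 497, 950 and 23.3 FPKM), while H2-Eb1 and Cd74 varied by 1.17 and 1.18 times between the lowest and the highest library.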

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

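The comparison by the table of means, the 4-library comparison, voom and the length correction were chosen after seeing the data. By the labels the count of called genes was 0 under every setting fixed before the data were examined, at an adjusted p of 0.1 too, and under voom and length correction. It was 2 in the 4-library comparison (Ighd5-3 and Ighd2-3) and 3 with the table sets. The 8 called lists became 5 at a mean FPKM of at least 5, 15 in the 4-library comparison, 14 with the table sets, and 0 with an estimated correlation and with fry. Leaving out 1 library gave 4 (without WT replicate 2) to 12 lists. Cd40lg, at -0.14 FPKM by the labels, lay between -0.257 and -0.067 when 1 library was left out and turned to 0.326 with the table sets. The cause of these changes was not tested beyond the change of libraries itself.

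With the table sets the 3 called genes became 5 at a pseudocount of 0.1, 1 without a filter, 0 at a mean FPKM of at least 5, 1 after quantile normalization, 6 with robust variances, 11 with array weights, 1 with voom, 0 after length correction and 8 at an adjusted p of 0.1. Leaving out 1 library gave 1 to 16. The filter at a mean of 5 FPKM removed all 3 genes from testing, which explains the 0. The 14 lists stayed between 11 and 17 in all other settings, and fell to 0 with an estimated correlation and with fry. The cause of the other changes was not tested.

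Replicate numbers did not pair the libraries in general: the deviations of same-numbered libraries correlated at -0.38, 0.06 and 0.38 across genes (genes are not independent). The value of 0.38 for number 3 was the highest for both of its libraries, though WT replicate 3 reached 0.36 with CD40LΔ5 replicate 1. WT replicate 1 went most with CD40LΔ5 replicate 2 (0.56). With the number as a block 0 genes and 9 lists were called, and Cd40lg stayed at -0.14.

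Lists that turned direction and were called before or after the turn are given with their adjusted p; turns without a call on either side are only counted, among those that moved. With the table sets these were dark zone (1.5e-10), T cell (0.0295), natural killer cell (1.2e-07), monocyte and macrophage (0.000405), neutrophil (0.000143), erythroid (0.0349) and stroma genes (0.0349). In the 4-library comparison they were germinal centre (3.6e-06), cell cycle (1.6e-14), plasma cell (5.0e-05), endoplasmic reticulum folding (0.000269), switched constant region (0.0142), interferon response (1.3e-15), MYC targets (0.958) and glycolysis (0.266). Array weights turned neutrophil genes (0.000625). Without WT replicate 1, dark zone (0.00585) and macrophage genes (0.757) turned. Without WT replicate 3, germinal centre (0.0377) and plasma cell genes (0.942) turned, and without CD40LΔ5 replicate 1 erythroid genes (0.408). Without CD40LΔ5 replicate 2, germinal centre (0.0195), cell cycle (0.000107), plasma cell (0.417), endoplasmic reticulum folding (0.369), interferon response (4.2e-06) and glycolysis genes (0.704) turned, and without CD40LΔ5 replicate 3 neutrophil genes (0.000198). With the table sets, erythroid genes turned without CD40LΔ5 replicate 1 (0.786). When 1 library was left out by the labels, the adjusted p ranged from 3.8e-06 to 0.658 for germinal centre, 0.000132 to 0.680 for dark zone, 3.0e-12 to 0.659 for cell cycle, 9.3e-14 to 0.942 for plasma cell and 5.1e-11 to 0.850 for endoplasmic reticulum folding genes. It ranged from 6.3e-09 to 0.942 for interferon response, 0.00152 to 0.704 for glycolysis, 5.4e-17 to 0.757 for macrophage, 7.4e-05 to 0.859 for neutrophil and 5.1e-11 to 0.408 for erythroid genes, and with the table sets from 6.1e-07 to 0.786 for erythroid genes. The cause was not tested.

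For lists by the labels, 470 list results in other settings kept direction and side of the threshold, 51 lost the call, 45 gained one and 63 moved without a call. With the table sets these counts were 495, 48, 21 and 32. Among named genes by the labels, 1148 results kept direction and side and 63 moved. With the table sets 344 kept both, 17 lost the call and 13 gained one. Map3k19 and Rgs18 both lost their calls without a filter, after quantile normalization, after length correction and in the 4-library comparison, and Rgs18 with voom. A sex covariate was not run, since all libraries looked alike in sex-linked genes, and the count model foreseen for recovered reads was not run, with voom in its place. Robust variances do not apply to camera, and pseudocounts, filters and variance settings do not apply to the permutation test of Cd40lg. Its 4 to 17 reads per library limit that result.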

Other observations

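The tests in this part were chosen after the results were seen. Beyond the response genes, the libraries carried genes of granulocytes unevenly: Prg2, the major basic protein of eosinophils and listed here with plasma cell genes, stood at 140 and 121 FPKM in WT replicate 3 and CD40LΔ5 replicate 3 and at 17.9 to 38.5 FPKM in the others. Camp, a granule peptide of neutrophils chosen after its values were seen, stood at 27.4 and 66.5 FPKM in the same libraries and at 3.18 to 7.97 FPKM elsewhere. Hspa1b, a heat shock gene next to Hspa1a, stood at 21.3, 33.4 and 13.3 FPKM in WT replicates 1, 2 and 3 and at 15.5, 50.6 and 8.05 FPKM in CD40LΔ5 replicates 1, 2 and 3.

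In the first pattern, that of MHC genes on chromosome 17 between 33900000 and 37500000, 8 of 117 tested genes were lower in WT replicate 2 than in every other library by at least 1 log2 unit, against 6 of 11135 elsewhere. With the genes named H2- left out, 2 of 94 (Vars and Gm20506) stayed, and the share was still higher than elsewhere (one-sided Fisher exact p = 0.00188). H2-Bl, chosen after its values were seen like Vars and Gm20506, ran the opposite way, at 7.95 FPKM in WT replicate 2, 2.56, 3.39 and 1.14 FPKM in WT replicate 1, CD40LΔ5 replicate 2 and CD40LΔ5 replicate 3, and 0.06 and 0 FPKM in WT replicate 3 and CD40LΔ5 replicate 1. A lower output of the class II pathway as a whole is argued against, since the other 9 members of that list differed in WT replicate 2 by a median log2 of -0.15 where H2-Aa and H2-Ab1 differed by -1.61, although H2-DMb1 among the 9 was at -1.05. A candidate explanation is that the mice carried different MHC haplotypes, with alleles that differ from the C57BL/6 reference and take fewer of its reads; regulation in cis, and reads shared between MHC paralogs, were not tested and stay open.

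The second pattern is the disagreement between labels and table, which place 2 of the 6 libraries alike. A single mislabelled sample cannot account for it, since only 2 of the 6 libraries are placed alike. Several misplaced libraries, in the labels or in the table, with or without exchanged group names, may do so. No value decides which source is right: Cd40lg rests on few reads, and the genotype was not read from the sequence. The column order of the deposited values per library follows the sets of the table and not the labels, but it names no group. Linked segments that differ between the animals are another possible source of the table difference, an idea that came from Map3k19, Tmem163, Ctse and Rnpep, which lie on chromosome 1 between 127486546 and 135284084. Among the 30 genes of smallest p there were 10 pairs within 5 Mb, a count that includes these genes and so is no test of the idea, and 3 of the 10 splits, that of the table included, gave as many (highest of the others 12). The close genes also included Hspa1a and Ddah2 on chromosome 17 (34969190 to 35062095), inside the MHC stretch of the first pattern. Others lay on chromosomes 11, 14 and 19. Linked segments and the biological explanation, a difference between CD40LΔ5 and WT, both remain open.

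The third pattern is the lower oxidative phosphorylation and erythroid lists in the libraries labelled CD40LΔ5. The table difference had a trend with gene length (Spearman -0.23 across 11252 genes, which are not independent replicates). It was -0.33 for WT replicates 1 and 2 and CD40LΔ5 replicate 3 against the rest, a split that neither source gives. The label difference had such a trend too (Spearman 0.32 across the same genes), and oxidative phosphorylation genes are short. After removal of that trend in each library these lists kept their camera calls, with adjusted p = 0.00297 for oxidative phosphorylation (mean log2 difference -0.09 before and -0.08 after) and adjusted p = 0.000464 for erythroid genes (-0.33 before and after), which argues against gene length as the whole cause. The same removal ended the calls of T cell genes (adjusted p = 0.239; mean log2 difference -0.07 ± 0.08 before and -0.06 ± 0.09 after, SD over 16 genes) and glycolysis (adjusted p = 0.126; -0.05 ± 0.07 before and -0.06 ± 0.07 after, SD over 16 genes) and brought one for interferon response (adjusted p = 0.0266). The oxidative phosphorylation and erythroid calls ended with an estimated correlation (adjusted p = 0.879) and when single libraries were left out, so they may rest on which libraries stand in each label.

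With 3 against 3 libraries there are 10 splits, which cannot give a share under 0.1. By the labels the real split called 0 genes and the highest other split 3; all 10 of the 10 splits give at least 0, so this count decides nothing. It called 8 lists and the highest other split 16, and 8 of the 10 splits gave as many. By the table sets the real split called 3 genes and the highest other split 1, so 1 of the 10 splits, the real one, gave as many. It called 14 lists and the highest other split 16, and 3 of the 10 gave as many. At an unadjusted p under 0.05 the label split had 139 genes against 563 expected, while another split, which is neither that of the labels nor that of the table, had 1458 beside the 1463 of the table split.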
